A study of Mus musculus with 2 samples.

How the data were processed

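Guide abundance in a pooled CRISPR knockout screen was measured in 2 populations of Cas9-expressing immortalised mouse macrophages, uninduced input cells and doxycycline-induced sorted survivors, with 1 library each. Groups were taken from the treatment label of each sample. Per the labels' protocols, genomic DNA was purified, cleaned of PCR inhibitors, and the guide barcodes were amplified by PCR and sequenced on an Illumina instrument. The authors deposited whole-number raw read counts per 20-base guide barcode, with no normalization, per the file headers and the series design text. The counting tool, its mismatch setting and its version are not given in the sources used here. The headers and titles call the input library and the survivor file combined, and what was combined is not given in the sources used here. PCR reads without molecular identifiers are not independent molecules, so the floors and the intervals of single-guide ratios cover counting error only. The intervals of shares treat guides as independent draws and do not measure read-counting error.

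The counts of both libraries were joined by barcode. Total reads were 86266754 for the input and 16269091 for the survivors. Guides with fewer than 30 input reads, 2866 of 79633, were left out of fold changes. Counts were scaled to a library total of 1000000 (RPM) and a pseudocount of 1 RPM was added. The log2 fold change of survivors over input was centred on the median of all kept guides. Non-targeting guides were not identified, as neither a guide annotation of the library nor a genome was used here. The median log2 fold change before centring was -0.42. With 1 library per group no replicate-based model was fitted. edgeR and DESeq2 were used only for scaling factors (TMM and median of ratios), as alternatives.

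The design written before the data were examined planned a gene-level permutation test over guides, 29 gene lists and a rule for named genes. These needed a gene for each guide. The count files list sequences only, and neither a guide annotation of the library nor a genome sequence was used here. The gene tests, the lists, the named-gene rule and their 28 alternatives were therefore not run. The guide-level analyses reported were chosen after the files were seen, except the library measures and the guide log2 fold change; the 4-fold threshold on it was also chosen afterwards. The rule applied to single guides was the 2 highest and the 2 lowest log2 fold changes.

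Sampling of the survivors was described from the share of guides with 0 survivor reads in 20 equal bins of input reads and from the maximum-likelihood fit of P(absent) = exp(-c × input reads), with 200 bootstrap draws over guides. Binomial thinning of the input to 18.9% gave the spread from reading fewer of the same reads. The thinned reads were compared with the input they came from, so this spread is below that of 2 independent read counts. Overlapping guides were pairs sharing at least 14 bases end to end on the same or opposite strand. The pair correlation was computed over both orders of each pair, with 2000 bootstrap draws over clusters of connected guides, and joint counts were compared with 1000 draws of guides from the same bins. Base effects were computed on recovered guides after subtracting the mean of their input bin. Exact Clopper-Pearson intervals at 95% were used for shares and, through the conditional binomial, for ratios of 2 counts.

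The sampling fit, the pair correlation and the base effect were tested on simulated data with 4 units per 1000 input reads, a first-base G effect of -0.5 and shared 4-fold changes in pairs of overlapping guides. The fit returned 3.75 units and a log-log slope of 0.99 with no shared change, so it reads slightly low. The G to T difference came back as -0.46, -0.51 and -0.46 in the 3 simulations. The pair correlation over 764 pairs was 0.036 (95% interval -0.027 to 0.11) with no shared change, 0.078 (0.0033 to 0.14) with 50 changed pairs, and 0.31 (0.24 to 0.37) with 200 changed pairs. Alternatives covered the input minimum, the pseudocount, the scaling, the overlap length, the strand, the definition of absence and centring within bins of input reads, GC content or first bases. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.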

Results

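The data came from a pooled CRISPR knockout screen in mouse macrophages. The cells were bone marrow derived macrophages that carried Cas9, had been immortalised with the J2 retrovirus, and expressed a tetracycline-controlled transactivator. They also carried a doxycycline-inducible, BFP-tagged N-terminal fragment of gasdermin D (GSDMD). GSDMD is the pore-forming protein that executes pyroptosis, an inflammatory form of cell death, and its N-terminal fragment forms the membrane pore. The cells received the Brie library, a genome-wide mouse library of single guide RNAs (sgRNAs), and the abundance of each guide was read from genomic DNA by amplifying and sequencing its 20-base barcode. According to the series title, the question was which pathways control GSDMD oligomerisation and pyroptosis, with the Ragulator-Rag-mTORC1 pathway named. The 2 populations were given, each as 1 library: uninduced input cells, and cells that were induced with 0.5 μg/ml doxycycline for 16 h and sorted as BFP positive and propidium iodide negative, the stain that enters cells with broken membranes. The design therefore had 1 sample per group, no difference reported here has a replicate check, and no p-value is given. The counts name guides by sequence only and were not paired with genes here, so no result is given for Lamtor, Rag or any other gene.

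The induced survivors held a narrower library than the uninduced input. Both libraries listed the same 79633 guides. The input held 86266754 reads with a median of 939 reads per guide, and the survivors held 16269091 reads with a median of 126. In the input 1272 guides had no reads, which is 1.60% of the library (95% exact binomial interval 1.51 to 1.69%), and in the survivors 10573 guides had none, which is 13.3% (13.0 to 13.5%). The Gini coefficient of reads per guide, which is 0 when all guides are equal, was 0.394 in the input and 0.577 in the survivors. The top 796 guides took 3.95% of the input reads and 7.07% of the survivor reads. A count of 0 allowed an abundance of up to 0.0348 RPM (reads scaled to a library total of 1000000) in the input and 0.184 in the survivors. These floors cover counting error only. The binomial intervals of shares treat guides as independent draws, and measure neither read-counting error nor the spread between replicate libraries. Guide abundance in the survivors followed the input, with a Pearson r of 0.672 on log2(RPM + 1) and a Spearman rho of 0.661 across the 76767 guides that had at least 30 input reads. These correlations are across guides, which are not independent replicates.

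**Figure D1:**
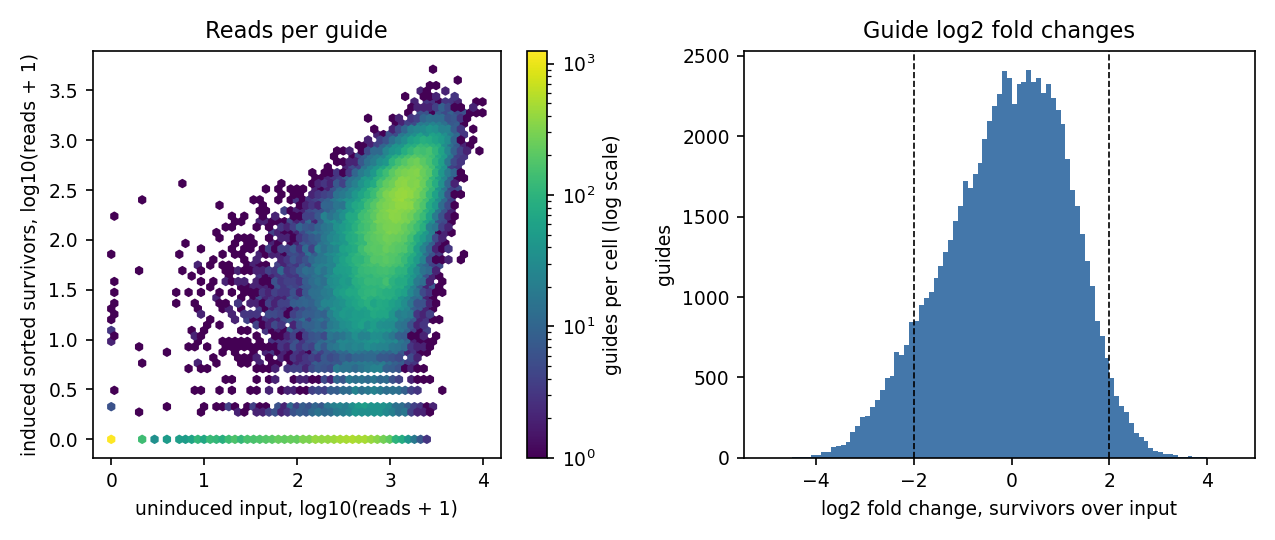
Left, reads per guide in the uninduced input (x axis) and in the induced sorted survivors (y axis), both as log10(reads + 1), with colour for the number of guides in each cell. Right, number of guides against the log2 fold change of survivors over input for the 76767 guides with at least 30 input reads; dashed lines mark 4-fold changes, passed by 2335 guides upward and 6272 downward.

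Induction and sorting were compared with the input guide by guide. Among the 76767 guides kept, 2335 were at least 4-fold more abundant in the survivors, relative to the median guide, which is 3.04% (95% exact binomial interval 2.92 to 3.17%). At least 4-fold lower were 6272 guides, which is 8.17% (7.98 to 8.37%), and 2891 of these had no survivor reads. With the pseudocount, guides with few input reads could not pass 4-fold down even with no survivor reads. The count therefore holds only 2891 of the 7876 kept guides that were absent from the survivors. The SD of the log2 fold changes over guides was 1.25, with a 5th percentile of -2.34 and a 95th percentile of 1.78. The spread was far above that from thinning the input. The input reads thinned at random to the survivor total gave an SD of 0.098 (mean of 20 draws) and no guide past 4-fold in either direction. The thinned reads are part of the input they were compared with, so this SD is below that of 2 independent read counts. The counts past 4-fold depended on the scaling: with edgeR's TMM factors, which moved the median log2 fold change to -0.23, they were 1361 up and 8899 down, and with DESeq2's size factors, which moved it to -0.18, they were 1532 up and 8567 down. The larger number of guides below than above 4-fold did not hold with a pseudocount of 5 RPM, which gave 437 up and 156 down, while a pseudocount of 0.1 RPM gave 3387 up and 14237 down.

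The guides at either end show what these values rest on. The largest log2 fold change, 4.21, belonged to the guide AGGACGATGTAGATCAGGGT, with 595 input reads and 1767 survivor reads. Its ratio without a pseudocount, centred on the same median as the log2 fold changes, was 4.40 on the log2 scale (95% exact interval 4.26 to 4.53). That median was itself computed with the pseudocount, and the ratios of the guides below were centred in the same way. The next, at 4.20, was TGCTCGGTCCAGAAAGTCGA, with 48 input reads and 331 survivor reads and a ratio without a pseudocount of 5.61 (5.17 to 6.08). The lowest value, -4.90, belonged to CTGTCAAGAAGTGTCCCGTG, with 3774 input reads and 2 survivor reads, whose ratio without a pseudocount was -8.06 (-11.1 to -6.20). The guide TCAATCAGGCTAAGTCTGAA followed at -4.63, with 2946 input reads and 1 survivor read and a ratio of -8.70 (-14.0 to -6.22). The genome positions and genes of these 4 guides were not analysed here. They were chosen as the 2 highest and 2 lowest after the values were seen, and their intervals cover counting error only.

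Guides with few input reads were the ones most often lost from the survivors. Of the guides with at least 30 input reads, 7876 were absent from the survivors, or 10.3% (95% exact binomial interval 10.0 to 10.5%). In 20 bins of equal size by input reads, 66.7% of guides were absent in the bin with a median of 90 input reads, 13.8% at a median of 513 reads, 3.26% at a median of 1016 reads, and 0.156% at a median of 2337.5 reads. The input thinned to the survivor total left a mean of 0.5 guides at 0. A model in which each guide was sampled as a Poisson number of units in proportion to its input reads gave 3.79 units per 1000 input reads. That is a mean of 4.25 units per guide (95% bootstrap interval over guides 4.20 to 4.31) and 49.8 survivor reads per unit. In each bin with a median from 841 to 2337.5 input reads more guides were absent than the model gives. The shares were 3.26% against 2.15% at a median of 1016 and 0.156% against 0.0154% at a median of 2337.5. In the bin at a median of 90 fewer guides were absent than the model gives, 66.7% against 71.3%. A single number of units per 1000 input reads therefore does not describe all bins. The SD of the log2 fold changes within a bin rose and then fell with input reads: it was 0.959 at a median of 90 input reads, where most guides were absent from the survivors, 1.39 at a median of 513, and 0.965 at a median of 3040.

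**Figure D2:**
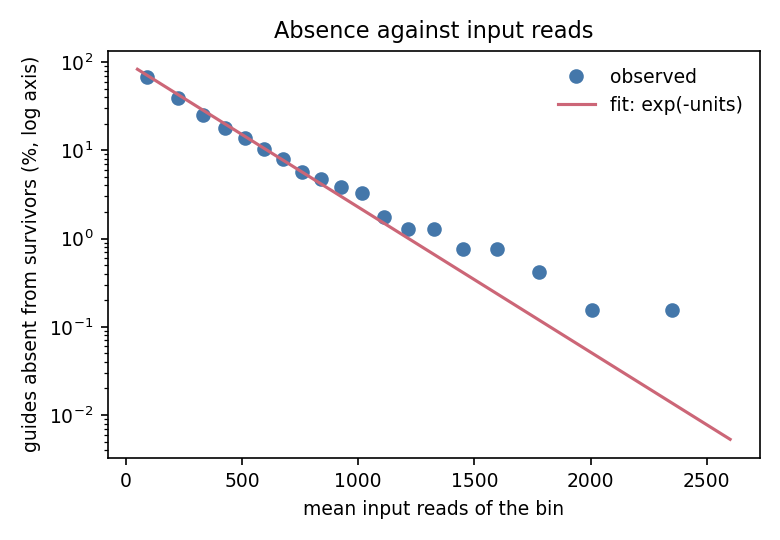
Percentage of guides absent from the survivors (y axis, log scale) against the mean input reads of each of 20 equal bins of guides (x axis); points are the observed shares, 1 bin with no absent guide is not drawn, and the line is the sampling model with 3.79 units per 1000 input reads. Absence fell from 66.7% in the lowest bin to 0.156% in the 2 highest bins drawn, where it lies above the line.

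Guides whose sequences overlap were taken as directed to nearly the same place and served as an internal comparison that needs no gene names. No genome was used, so the shared target of a pair was not checked. Sharing at least 14 consecutive bases on the same or the opposite strand, 917 pairs formed from 1553 guides, of which 500 pairs lay on the same strand and 417 on opposite strands. When opposite-strand overlaps were sought in reversed rather than reverse-complemented sequences, as a chance control with the same bases, 39 pairs were found. The pairs on the same strand had no such control. In the uninduced input the guides of a pair had similar read numbers, with a pair correlation of 0.54 (95% bootstrap interval over clusters of overlapping guides 0.46 to 0.62) and a Spearman rho of 0.45. Among guides from 30 input reads, the set used for fold changes, the pair correlation of input reads was 0.37 (0.30 to 0.44). Their survivor reads, which carry the input abundance, had a pair correlation of 0.30 (0.23 to 0.37). Their log2 fold changes had no detectable correlation in these libraries. The pair correlation was 0.0078 (-0.057 to 0.074) over the 764 pairs with both guides at 30 or more input reads, and rho was -0.00039. Both guides were in the top 10% of fold changes in 10 pairs, where random guides of the same input bins gave a mean of 8.41 (95% of draws 3 to 14). Both were in the bottom 10% in 8 pairs, against 7.74 (3 to 13). In the 121 pairs with at least 1000 input reads in both guides the correlation was 0.106 (-0.042 to 0.247). The correlations are across guide pairs within 1 pair of libraries, and those of input reads and of fold changes were recomputed under other overlaps, strands and read minimums.

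**Figure D3:**
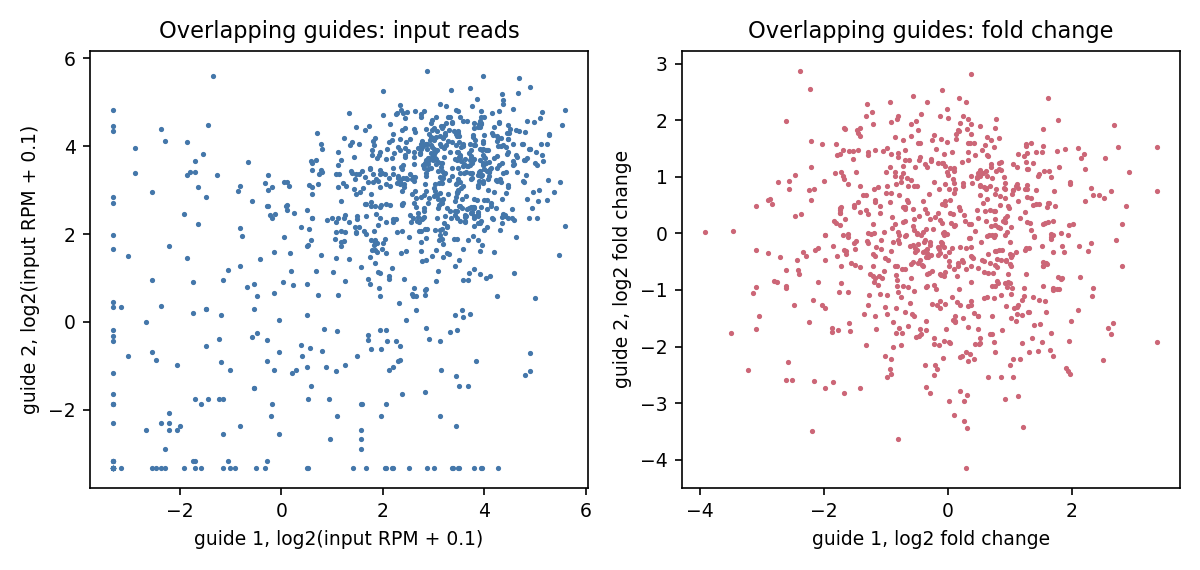
Each point is 1 pair of guides whose sequences share at least 14 bases on the same or the opposite strand. Left, log2(input RPM + 0.1) of one guide against the other, 917 pairs with r = 0.54 (0.37 among guides from 30 input reads). Right, log2 fold change of survivors over input of one guide against the other, 764 pairs from 30 input reads with r = 0.0078.

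The first base of the guide went with the number of survivor reads. At matched input reads, guides that started with G and were recovered in the survivors had a mean log2 ratio of -0.35 (SE over guides 0.011, n = 19416) relative to their input bin. Guides starting with A had 0.0096 (SE 0.011, n = 17925), C 0.20 (SE 0.012, n = 15929) and T 0.22 (SE 0.012, n = 15621). The difference between G and T was -0.57 (SE 0.017), or 1.49-fold, and G was below T in 20 of 20 input bins. Among all kept guides, without matching on input reads, the share past 4-fold up was 1.46% for those starting with G and 4.41% for those starting with T. Their median input reads were 893 and 1037. The bases at positions 1 to 6 held 95.1% of the summed variance explained by single positions, and no position from 7 to 20 explained more than 0.0692%. Most of the variance was not explained by these bases. Position 1 explained 2.25%, and the first 4 bases together explained 3.68% after adjustment for the number of base combinations. By GC content, the median log2 fold change was -0.19 for guides with 35% GC or less, 0.074 for guides with 60 to 65% and 0.021 for guides with 70% or more, whose median input reads were 688, 1128 and 1160.5. After centring within the input bins these medians were -0.094, 0.023 and -0.032.

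**Figure D4:**
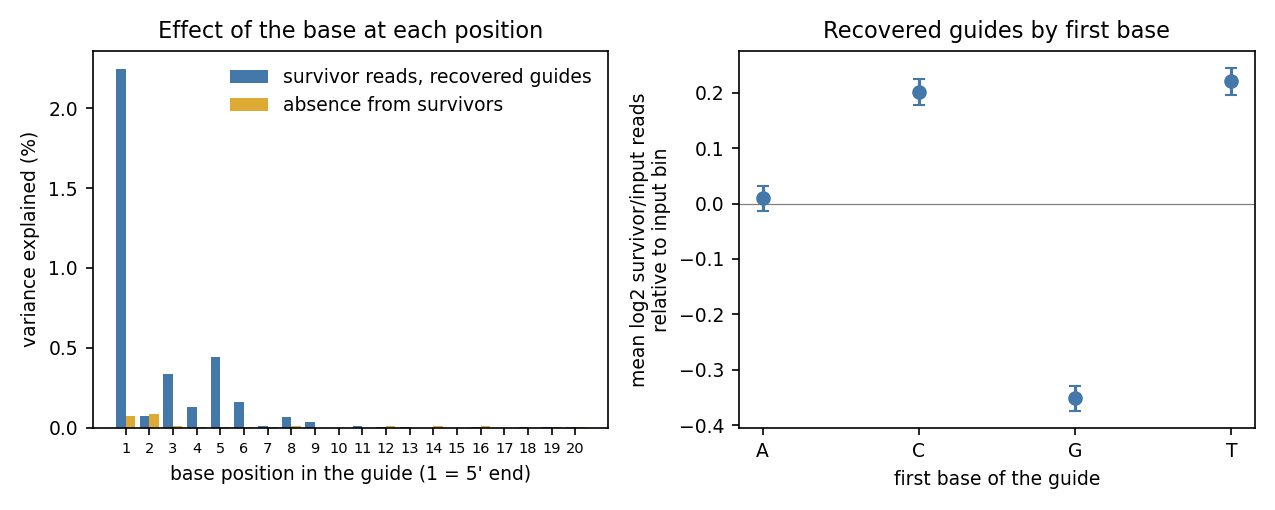
Left, percentage of variance explained by the base at each of the 20 guide positions (1 is the 5′ end) in the survivor reads of recovered guides and in absence from the survivors, both at matched input reads; position 1 explained 2.25% of the former. Right, mean log2 ratio of survivor to input reads relative to the input bin by first base, with bars of 1.96 SE over guides: G at -0.35, A at 0.0096, C at 0.20 and T at 0.22.

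Guides with certain short motifs were missing from the input itself. Of 215 guides that contained TTCGAA, 179 had no input reads, or 83.3% (95% exact binomial interval 77.6 to 88.0%). Of 401 guides that started with TCTC, 350 had none, or 87.3% (83.6 to 90.4%), while 26 of 4404 guides with TCTC at another position had none, or 0.59% (0.386 to 0.864%). Of 101 guides that started with AGACG, 77 had none, or 76.2% (66.7 to 84.1%), against 8 of 1030 with AGACG elsewhere, or 0.777% (0.336 to 1.52%). Of 14 guides with CGTCTC or GAGACG, 13 had none. Together 730 guides, 0.917% of the library, carried such a motif. Of these, 618 were absent from the input, which is 48.6% of all guides absent from it.

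**Figure D5:**
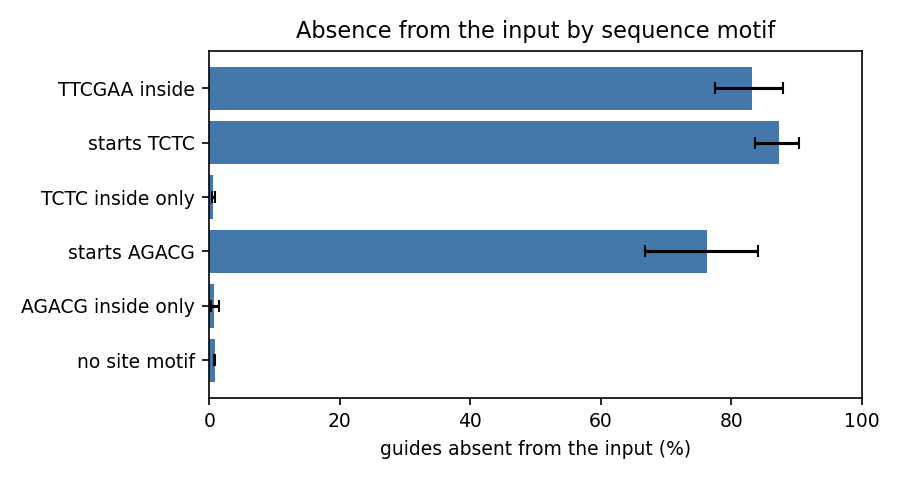
Percentage of guides with 0 input reads (x axis) among guides with each motif, with 95% exact binomial intervals as bars. Guides that contained TTCGAA or started with TCTC or AGACG were absent in 76.2 to 87.3% of cases, guides with TCTC or AGACG at another position in 0.59 and 0.777%.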

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

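Of the tests below, the thinning, the slope, and those on the first base were chosen after the result was seen, and those on overlapping pairs were written before their result.

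Among guides with 0 input reads, 21 had survivor reads, and 14 of these had more than 3, the floor of the survivor library (0.184 RPM), where a count of 0 in the input allows up to 0.0348 RPM; the highest had 168. These guides lie outside the fold changes, and 2 of the 21 differ from another guide of the library by 1 base.

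Absence from the survivors. With at least 30 input reads, 7876 guides had no survivor reads. Shallower sequencing is argued against by the thinned input, which left a mean of 0.5 guides at 0. Narrow sampling of cells or of DNA templates before sequencing is consistent with the rise of minus ln(share absent) with input reads, whose log-log slope was 0.86 (95% bootstrap interval 0.84 to 0.89) over the 19 bins with absent guides, where simulated sampling in strict proportion gave 0.99. Loss of guides that share a target, as the main cause, is argued against by overlapping pairs: both guides were absent in 29 of 764 pairs, 0.896 times the mean for input-matched random guides (95% interval 0.556 to 1.30), which does not bear on loss at a few targets. This takes overlapping guides as sharing a target, which was not checked against a genome. Whether the sampled units were surviving cells or DNA copies taken into PCR stays open, because both would give the same counts.

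First base of the guide. At matched input reads, guides starting with G were absent less often than guides starting with T. The difference was -1.66 percentage points (95% interval -2.18 to -1.15), although the survivor reads of guides starting with G were lower. Without matching, 10.4% of guides starting with G and 10.2% of those starting with T were absent. The matched difference argues against an effect of the guide on survival only if input reads stand for cells equally for both first bases. That condition was not tested. A difference in input reads as the cause is argued against by G lying below T in all 20 input bins, under the same condition. A first-base bias in how the input itself was read would also act in every bin and is not argued against. Median input reads were 893 for guides starting with G and 1037 for those starting with T. A difference in the reads obtained per recovered guide, through amplification, sequencing or barcode counting, stays open: the 95.1% of the per-position variance in positions 1 to 6 is the pattern itself and decides nothing. An effect of the first base on guide transcription in cells that survived was not tested.

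Overlapping guides agreed in input reads and not in fold change. Shared base composition as the cause of the agreement is argued against by the pair correlation of 0.571 (95% interval 0.485 to 0.645) after a model of the base at each position and GC content, which explained 5.23% of the variance of input reads. That model holds single bases and GC content only, so an effect of longer stretches shared by overlapping guides was not tested by it. In 130 of 917 pairs both guides had under 200 input reads, 13.9 times the mean of draws matched on composition (95% interval 10.7 to 17.5). The ratio met the criterion written beforehand for loss, before induction, of guides that share a target. It does not decide on that cause, since any cause of agreement in input reads would raise it. The draws came from the whole library, so a higher share of guides with few input reads among overlapping guides would raise it too. A shared start in the plasmid pool, which was not analysed here, would give the same. Whether sampling noise hides a shared change in the survivors stays open, since the correlation of 0.106 in pairs with at least 1000 input reads has an interval from -0.042 to 0.247. The upper bound of the correlation over all 764 pairs allows a change shared by overlapping guides with an SD of up to 0.34 on the log2 scale, or 1.27-fold, and strong changes at few targets stay within it.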

How the results depend on the processing

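No paired analysis was possible because each group had 1 library and the labels give no shared replicate numbers; for the same reason no replicate could be left out. The 28 alternatives planned for gene tests, named genes and gene lists were not run, because guides were not paired with genes here. All alternatives below were added after seeing the data; 31 of 40 stayed within the interval of the main value or, for counts, within 1.5 times of it. The count of guides at least 4-fold up, 2335, moved to 437 with a pseudocount of 5 RPM, 1361 with TMM scaling and 1532 with DESeq2 size factors; the last 2 shifted the median by -0.23 and -0.18. The count at least 4-fold down, 6272, moved to 14237 with a pseudocount of 0.1 and to 156 with 5, as a larger pseudocount pulls low counts together. Units per 1000 input reads moved from 3.79 to 3.41 when up to 2 survivor reads counted as absent. The pair correlation of fold changes lay between -0.020 and 0.042 under the other alternatives and moved to 0.106 from 1000 input reads; the cause was not tested. The pair correlation of input reads moved from 0.54 to 0.37 among guides from 30 input reads, a narrower range by construction, and was 0.57 without guides carrying a restriction site motif. Absence of motif-bearing guides moved from 84.7% to 88.5% when up to 2 input reads counted as absent. The G to T difference stayed between -0.58 and -0.57. Under the sampling model, which gives fewer absent guides than observed at high input, the survivors held a mean of 4.25 units per guide and 49.8 reads per unit. Thinning the input to the survivor total gave a log2 fold change SD of 0.098 against 1.25 observed.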

Other observations

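The test of restriction sites was chosen after the result was seen; the test of the upper tail was written before its result.

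The motifs missing from the input match recognition sites of enzymes used in cloning. TTCGAA is the BstBI site, and CGTCTC, with its reverse complement GAGACG, is the BsmBI site. A guide starting with TCTC completes CGTCTC when the bases ahead of it are CG, and a guide starting with AGACG completes GAGACG when the base ahead is G, as in the common U6 guide vectors. As a hypothesis, these guides may have been cut and lost while the library was cloned: 84.7% of the 730 guides with such a motif were absent from the input, against 0.829% of the 78903 others, a ratio of 102. The position of the motif mattered, since TCTC and AGACG at other positions went with absences of 0.59% and 0.777%. Among 63 other palindromes of the same length, the highest share absent was 3.70%, for TATATA. The cloning steps are not given in the sources used here.

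A second hypothesis was that the guides enriched in the survivors exceed what sampling would give. Simulated libraries took their settings for each input bin from the observed mean, variance and share of absent guides, and no guide had an effect of its own. A simulated unit could also yield no reads, so more guides could be absent than observed, which was not checked. The simulations gave a mean of 2386 guides at least 4-fold up (highest of 100 simulations 2507), and the observed 2335 were 0.979 times the mean. The same simulations gave 7590 to 7924 guides at least 4-fold down against 6272 observed, and they take their variance from the same libraries, which would include any selection, so the ratio decides nothing and selection in the upper tail stays open. The ratio alone would have met the criterion written beforehand for sampling noise; the lower tail and the shared variance were weighed after the result was seen. Agreement between guides of 1 gene was not analysed here.

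Reads of 1 exceeded reads of 2 in both libraries: 911 guides had 1 survivor read and 222 had 2, and 143 had 1 input read and 35 had 2.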
